A study of Staphylococcus aureus with 12 samples.

How the data were processed

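RNA sequencing of Staphylococcus aureus cells gave 12 libraries in 4 groups of 3, per the labels LJN, BITC, RES and BITC_RES. Per the submitters, total RNA was extracted with the RNAprep Pure Cell/Bacteria kit and mRNA was enriched. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 without giving their roles. The design text of the submitters instead names Bowtie2 for alignment, and DESeq2 for testing, so the aligner is stated in 2 ways. The strand setting of the counting is not given in the sources used here.

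The values used were the FPKM (fragments scaled for gene length and library size) of each library as deposited by the authors in 1 table of 3166 features. These comprise 2872 annotated genes, 268 features without an annotated gene and 26 small RNAs. The FPKM values were checked against whole reads. For each library, a denominator was found that turns 100% of its nonzero values into whole reads within 0.01. The denominators equalled a median-of-ratios size factor over the 2657 features with reads in every library times 6946443 reads, with a deviation of at most 1.7e-11, so the deposited values were already scaled between libraries. The group columns of the authors equalled the replicate means, with a relative difference of at most 2.1e-08, and were not tested. Recovered reads ranged from 6365778 to 7421873 per library.

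Gene symbols came from the gene name column of the deposited table (219 features), a synonym in the reference table (8) and the table's best protein hit in Staphylococcus aureus (680). The 68 features that shared a symbol with another were given none, which left 839 features with a symbol. No genome sequence was used, so sequence-based questions such as GC content were not analysed here.

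Features with a mean of at least 1 FPKM over the 12 libraries were tested, 2755 in all, and 411 were left out. Values were transformed to log2(FPKM + 1), so log2 changes of genes near 1 FPKM are drawn toward 0. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3), with moderated variances that follow the mean level. The p-values were adjusted by Benjamini and Hochberg within each comparison, and an adjusted p below 0.05 was called a change. Each pair of groups was compared, and 1 contrast set BITC_RES minus BITC against RES minus LJN. Log2 changes are given ± SE, and FPKM as mean ± SD with n = 3.

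In all, 33 gene lists were matched to the features by symbol, apart from the stable RNA list, which was matched by gene type. Coverage differed between lists. Matches were found for 51 of 54 ribosomal protein and 23 of 23 aminoacyl-tRNA synthetase symbols. They were found for only 8 of 25 toxin, 5 of 21 efflux, 3 of 14 bacillithiol, 5 of 18 cysteine and methionine and 8 of 35 capsule and biofilm symbols. The lists, the test, its threshold, the comparisons and the rule for naming genes were fixed before the data were examined. Lists with at least 4 tested members were tested with camera at a preset correlation between genes of 0.01, and p-values were adjusted over the lists. An estimated correlation and fry were the alternatives. Counts of list members use the p-values adjusted over all tested genes, and a second count adjusts over the list alone.

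Named genes followed a rule. For each comparison it takes the genes with a symbol that passed the test and whose groups did not overlap, up to the 12 largest rises and the 12 largest falls. For each list it takes up to 4 members with the largest absolute log2 change, passing or not. For the contrast it takes the 10 passing genes with the largest absolute value, and per comparison at most 2 risen and 2 fallen features without a symbol. The texts name a selection of these, and any other gene is marked as chosen after its values were seen.

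The test was also tested on simulated data, in which 200 genes were changed within libraries shaped like these. For BITC against LJN it recovered 50.9% of 1.5-fold, 87.5% of 2-fold and 98.6% of 4-fold changes, and 2.99% of its calls were false. For RES against LJN the values were 49.3%, 82.3%, 92.5% and 7.5%, and for BITC_RES against LJN 54.3%, 85.7%, 95.5% and 3.73%. For the contrast they were 27.9%, 63.0%, 84.7% and 2.54%. Of the other comparisons, BITC_RES against BITC had 6.63% false calls, BITC_RES against RES 3.95% and RES against BITC 4.27%. Each comparison was simulated once and with the known denominators. These rates therefore cover neither an error in the scaling nor comparisons in which more genes changed.

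Alternatives tried were pseudocounts of 0.1 and 10, no filter, a filter at a mean of 10 FPKM, rescaling to TPM, median-ratio scaling and quantile normalization. Others were variances without a trend, robust variances, a fit of the compared groups alone, a block for the replicate number, leaving out each library and a threshold of at least 2-fold. Added after seeing the data were limma-voom on recovered reads, each library's own read total, annotated genes alone, symbols from protein hits in other species, and list tests without BITC replicate 3. The replicate numbers were checked for pairing. Deviations from group means correlated at -0.308 to 0.191 between libraries of the same number, so the numbers were not taken to pair libraries. Statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.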

Results

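The series measured transcript levels in Staphylococcus aureus, a Gram-positive pathogen, with 12 RNA sequencing libraries made from bacterial cells. The labels place 3 libraries in each of 4 groups named LJN, BITC, RES and BITC_RES. BITC is benzyl isothiocyanate, an electrophilic plant isothiocyanate, RES is resveratrol, a plant stilbene, and BITC_RES is named for both. LJN is taken as the control because it is the only group not named for a compound of the series title. The title asks about a joint antibacterial action of both compounds. Doses, exposure times and the strain are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

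Between 6365778 and 7421873 reads per library were assigned to 3166 features, of which 2755 were tested. Positions refer to the chromosome of the NCTC reference strain, as the deposited table gives them. Replicates of a group correlated at 0.980 to 0.990 (Pearson r across genes, which are not independent replicates). On the first principal component, which held 56.2% of the variance, the BITC_RES libraries lay at 38.3 to 41.2 and the BITC libraries at 8.25 to 14.5. The RES libraries lay at -25.5 to -23.5 and the LJN libraries at -28.5 to -26.3. The second component held 24.6% of the variance and set BITC, at -33.5 to -25.6, apart from the other groups.

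One small RNA, sRNA00010 at 788312 to 788631 on the plus strand, took 12.3 ± 0.312% of assigned reads in LJN (mean ± SD, n = 3 here and for all group values). Its share was 14.2 ± 0.748% in RES, 7.08 ± 2.60% in BITC and 5.08 ± 0.224% in BITC_RES. Within BITC, replicate 3 stood apart with 10.05% against 5.21% and 5.97%, and it was also the BITC library nearest to LJN on the first component. The 268 features that carry no annotated gene took 3.26 ± 0.585% of reads in LJN, 1.40 ± 0.0467% in BITC, 1.79 ± 0.166% in RES and 1.97 ± 0.723% in BITC_RES. Of these features, 264 overlap an annotated gene on the opposite strand. The strand setting of the read counting is not given in the sources used here, so values of genes with such an overlap are less certain. Among the genes named here these are arcA, arcB, arcC2, arcR, argG, argH, rocA, hly, hlgA, hlgB, sbi, saeR, vraR, lexA, hrcA, groEL, ahpC, gapA1, tpiA, icd, mqo1, qoxD, atpC, azoR, rbsD, rbsK, rbsU, SAOUHSC_00195 and SAOUHSC_00708. Reads can also be shared within the spl proteases and within the leukocidin and gamma-hemolysin genes, which are families of similar sequence.

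**Figure D1:**
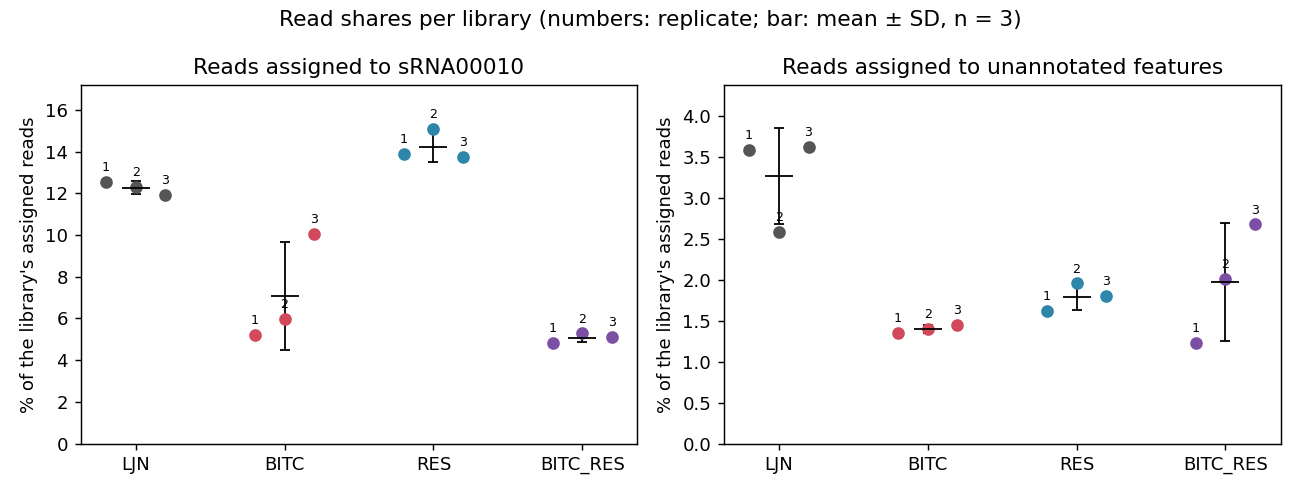
Percent of each library's assigned reads on sRNA00010 (left) and on the 268 unannotated features (right), with points for single libraries, their replicate number above, and bars for the mean ± SD of 3 libraries. BITC replicate 3 lies at 10.05% for sRNA00010 against 5.21% and 5.97% for the other BITC libraries, and LJN has the highest mean share of unannotated features, 3.26%.

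The comparison of BITC with LJN addresses the response to benzyl isothiocyanate alone. The arginine deiminase genes, which turn arginine into ornithine, ammonia and carbamoyl phosphate, and the urease genes, whose enzyme releases ammonia from urea, rose most among the genes with a symbol. arcA (SAOUHSC_02969, arginine deiminase, 2730276 to 2731511) went from 202 ± 15.5 FPKM in LJN to 3209 ± 827 in BITC, a log2 change of 3.95 ± 0.31 (SE, adjusted p = 7.09e-07). ureC (SAOUHSC_02561, catalytic subunit of urease, 2352985 to 2354700) went from 23.5 ± 0.802 to 404 ± 86.0 FPKM, a log2 change of 4.02 ± 0.16 (adjusted p = 3.92e-09). Some virulence genes fell, the toxin repressor gene rot by -3.68 ± 0.13, the quorum sensing response regulator agrA by -2.45 ± 0.10 and the alpha-hemolysin gene hly by -2.50 ± 0.09 on the log2 scale. ald1, for alanine dehydrogenase, and tdcB, for threonine dehydratase, which lie side by side, each fell by 5.07, from 368 ± 21.5 to 10 ± 1.63 FPKM for ald1 and from 329.7 ± 18.2 to 9.07 ± 2.67 FPKM for tdcB.

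In total 1631 of 2755 genes changed between BITC and LJN, 798 upward and 833 downward, and 645 of them by at least 2-fold. The 3 BITC values did not overlap the 3 LJN values in 65.1% of all tested genes, where chance gives 10%. After rescaling to TPM the direction counts became 1154 upward and 584 downward, with a median log2 change of 0.27 against 0.00, so the balance between rises and falls depends on the scaling. It also depends on the features. Of the 833 that fell, 202 were features with no annotated gene, and annotated genes alone in the fit gave 794 upward and 620 downward. Without BITC replicate 3 the count was 1736.

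Of the gene lists fixed before the data were examined, the arginine deiminase and urea list had 9 of 14 members higher in BITC and 5 lower (camera adjusted p = 0.00367, and adjusted p = 0.242 with an estimated correlation). The 9 were arcA, arcB and the genes ureA to ureG, and the 5, named after their values were seen, were argF, argG and argH of arginine synthesis with rocA and rocD of arginine use. The fall of argF did not pass with TPM (adjusted p = 0.109) or quantile normalization (adjusted p = 0.279). All 14 purine biosynthesis genes rose, with purQ at 1.93 ± 0.20 and purF at 1.71 ± 0.16 (adjusted p = 7.6e-06, and adjusted p = 0.242 with an estimated correlation). All 9 pyrimidine genes rose, led by pyrB, for aspartate carbamoyltransferase, at 1.72 ± 0.18 (adjusted p = 0.000773, and 0.418 with an estimated correlation). Of 15 heat shock genes 13 rose and none fell, among them the repressor gene hrcA at 1.17 ± 0.17, the disaggregase gene clpB at 0.94 ± 0.12 and, chosen after its values were seen, the chaperonin gene groEL at 0.82 ± 0.09 (adjusted p = 0.000431, and 0.402 with an estimated correlation). Sugar uptake genes rose in 13 of 19 cases and fell in 4, with uhpT, a hexose phosphate transporter, at 3.15 ± 0.15 and lacB of galactose-6-phosphate breakdown at 2.49 ± 0.30 (adjusted p = 0.0119, and 0.242 with an estimated correlation).

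Secreted toxin genes fell in 6 of 7 cases in BITC (adjusted p = 0.00318, and 0.242 with an estimated correlation). Secreted proteases, lipases and nucleases fell in 12 of 16 cases, including the thermonuclease gene nuc by -2.35 ± 0.21 and the aureolysin gene aur by -2.17 ± 0.22 (adjusted p = 0.00101, and 0.108 with an estimated correlation). Upward calls were also made for glycolysis with 9 up and 2 down of 12 (adjusted p = 0.0246, and 0.418 with an estimated correlation) and for aminoacyl-tRNA synthetases with 16 up and 2 down of 23 (adjusted p = 0.00227, and 0.592). The same held for ribosomal proteins with 22 up and 2 down of 51 (adjusted p = 0.00367, and 0.647) and peptidoglycan synthesis with 10 up and 1 down of 21 (adjusted p = 0.015, and 0.418). Fatty acid synthesis had 10 up and 0 down of 14 (adjusted p = 0.0246, and 0.444), and cysteine and methionine metabolism 4 up and 0 down of 5 (adjusted p = 0.0297, and 0.402), led by the methionine synthase gene metE at 2.21 ± 0.14. Counts depended on the scaling for ribosomal proteins, with 43 up and 0 down after rescaling to TPM, and for peptidoglycan synthesis, with 19 up and 1 down.

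Lists without a call in BITC against LJN were counted as well. Virulence regulators had 4 up and 8 down of 17 (adjusted p = 0.0628), TCA cycle genes 4 up and 9 down of 15 (adjusted p = 0.369), and staphyloxanthin and SigB-linked genes 0 up and 5 down of 8 (adjusted p = 0.0768). SOS response genes had 5 up and 7 down of 20 (adjusted p = 0.533), among them lexA, the SOS repressor, at -1.76 ± 0.17 and recA, for the recombinase, at -1.14 ± 0.09. Oxidative stress defence had 4 up and 3 down of 14 (adjusted p = 0.819), iron uptake 3 up and 0 down of 18 (adjusted p = 0.59), and copper, zinc and manganese handling 3 up and 0 down of 6 (adjusted p = 0.0768). Branched-chain amino acid genes had 1 up and 1 down of 9 (adjusted p = 0.712), and histidine, lysine and tryptophan genes 8 up and 4 down of 17 (adjusted p = 0.352). Fermentation had 3 up and 4 down of 10 (adjusted p = 0.941), the respiratory chain 0 up and 2 down of 9 (adjusted p = 0.712), and ATP synthase 5 up and 0 down of 8 (adjusted p = 0.0714). Teichoic acid synthesis had 4 up and 3 down of 16 (adjusted p = 0.712), autolysis 6 up and 0 down of 14 (adjusted p = 0.252), and surface adhesins 3 up and 6 down of 12 (adjusted p = 0.551). Capsule and biofilm genes had 2 up and 2 down of 6 (adjusted p = 0.64), multidrug efflux 1 up and 2 down of 5 (adjusted p = 0.712), and osmoprotection 4 up and 1 down of 7 (adjusted p = 0.104). The capsule count rests on 8 matched symbols of 35. All 14 genes from cap5A to SAOUHSC_00127, for capsule synthesis and chosen after their values were seen, fell in BITC. The stable RNA list, all tRNA genes here, had 3 up and 18 down of 42 (adjusted p = 0.0628). The bacillithiol list, with 1 up and 1 down of 2 members, was too small to test. Several of these counts turned after rescaling to TPM, which gave the TCA cycle 5 up and 4 down, oxidative stress defence 8 up and 1 down, the respiratory chain 4 up and 0 down, fermentation 4 up and 1 down, SOS response 5 up and 3 down and virulence regulators 6 up and 5 down. ATP synthase had 8 up after rescaling to TPM and 2 up with quantile normalization, and oxidative stress defence 6 up and 3 down with quantile normalization.

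Adjusted over the list alone, the BITC counts were the same for all lists but 7. These were heat shock with 14 up, iron uptake with 2 up, fermentation with 4 up and 4 down, ATP synthase with 6 up, ribosomal proteins with 20 up and 2 down, fatty acid synthesis with 11 up, and the secreted proteases list with 1 up and 12 down. The median, mean and camera direction differed in sign for oxidative stress defence (median -0.04, camera upward) and multidrug efflux (median 0.08, mean -0.08). For 13 of the 32 testable lists camera made a call with the preset correlation, none of these held with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, made 24 calls.

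The comparison of RES with LJN addresses the response to resveratrol alone. The gamma-hemolysin gene hlgA (SAOUHSC_02708, 2489229 to 2490158), which encodes a subunit of a pore-forming leukotoxin, rose from 219 ± 15.3 to 1505 ± 222 FPKM, a log2 change of 2.77 ± 0.13 (adjusted p = 3.72e-07). Its neighbours hlgC and hlgB rose by 1.09 ± 0.14 and 0.84 ± 0.10. The cell wall stress gene vraX rose from 12629 ± 1515 to 30519 ± 3316 FPKM, a log2 change of 1.27 ± 0.13 (adjusted p = 0.000219). The vitamin B6 synthesis gene pdxS rose by 1.23 ± 0.08, and SAOUHSC_02866, whose protein hit is a membrane protein of the MMPL family, by 2.51 ± 0.16. Of the 17 histidine, lysine and tryptophan biosynthesis genes 4 fell, a list call that an estimated correlation ended (adjusted p = 0.0155, and 0.746), with hisZ going from 97.9 ± 14.3 to 25.0 ± 16.2 FPKM and hisG from 51.3 ± 4.07 to 13.8 ± 5.50 FPKM, log2 changes of -2.13 ± 0.41 and -1.89 ± 0.29. The tyrosyl-tRNA synthetase gene tyrS changed by -1.28 ± 0.23 (adjusted p = 0.00466).

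Resveratrol alone changed 426 of 2755 genes, 190 upward and 236 downward, and 118 of them by at least 2-fold. Of the 236 that fell, 107 were features with no annotated gene. The groups did not overlap in 40.6% of all tested genes, against 10% by chance. With annotated genes alone in the fit the direction counts were 171 upward and 113 downward, and they were 92 and 280 after rescaling to TPM. The size of this count depended on single libraries. It was 623 without BITC replicate 3, a library of neither group compared. It was 208 without LJN replicate 1, 180 without LJN replicate 3, 234 without RES replicate 1 and 276 without RES replicate 2.

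Ribosomal protein genes fell in 23 of 51 cases and rose in 0, with rpsR at -0.54 ± 0.08 and rpsF at -0.54 ± 0.12 (camera adjusted p = 4.66e-10, and adjusted p = 0.746 with an estimated correlation). Adjusted over the list alone, 37 fell and 1 rose. TCA cycle genes rose in 5 of 15 cases, among them mqo1, for malate:quinone oxidoreductase, at 0.68 ± 0.10 and icd, for isocitrate dehydrogenase, at 0.65 ± 0.13 (adjusted p = 0.00553, and 0.746 with an estimated correlation). Respiratory chain genes rose in 4 of 9 cases, 6 adjusted over the list alone, led by the quinol oxidase gene qoxD at 0.71 ± 0.17 (adjusted p = 0.0131, and 0.746 with an estimated correlation). The rise of qoxD did not pass without LJN replicate 1 or 3 or RES replicate 2 (adjusted p = 0.0512, 0.0624 and 0.0594). Toxin genes rose in 3 of 7 cases and fell in 1 (adjusted p = 0.0117, and 0.746 with an estimated correlation). The 3 were the neighbours hlgA, hlgC and hlgB, of similar sequence, so the rises come from 1 locus. The gene that fell, sbi, encodes an immunoglobulin-binding protein and did not pass without any 1 of the LJN or RES libraries. Branched-chain amino acid genes fell in 4 of 9 cases (adjusted p = 0.0284, and 0.746), and the 4 histidine, lysine and tryptophan genes that fell were hisZ, hisG, hisD and hisH. The ribose uptake genes rbsD, rbsK and rbsU rose by 0.97 ± 0.09, 1 ± 0.11 and 0.97 ± 0.09, within a sugar uptake list that had 4 up and 0 down of 19 and no call (adjusted p = 0.289). The secreted proteases, lipases and nucleases had a median log2 change of -0.10 (adjusted p = 0.474) and the heat shock genes one of 0.07 (adjusted p = 0.614). Camera made 6 calls for RES, none of which held with an estimated correlation, and fry made 5.

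The comparison of BITC_RES with LJN addresses the response to both compounds together. Secreted virulence genes were among those that fell furthest. hly (SAOUHSC_01121, alpha-hemolysin, 1076413 to 1077372) went from 649 ± 20.9 to 17.2 ± 1.22 FPKM, a log2 change of -5.16 ± 0.09 (adjusted p = 4.34e-12), and hlgA from 219 ± 15.3 to 4.50 ± 0.475 FPKM, a log2 change of -5.33 ± 0.13 (adjusted p = 4.23e-11). splA (SAOUHSC_01942, a secreted serine protease, 1846654 to 1847361) went from 173 ± 20.9 to 1.06 ± 0.392 FPKM, a log2 change of -6.41 ± 0.21, and nuc from 92.2 ± 6.63 to 1.76 ± 0.582 FPKM. In the other direction, hrtB (SAOUHSC_02641, permease of the haem-regulated transporter, 2426796 to 2427851) rose from 2.12 ± 0.591 to 91.8 ± 26.4 FPKM, a log2 change of 4.88 ± 0.25 (adjusted p = 9.25e-09), and its ATPase gene hrtA by 3.85 ± 0.22. The mannitol transporter gene mtlA rose by 3.90 ± 0.19 and the glycolytic gene gapA1, for glyceraldehyde-3-phosphate dehydrogenase, from 3445 ± 70.7 to 31614 ± 978 FPKM, a log2 change of 3.20 ± 0.21.

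Both compounds together changed 1796 of 2755 genes, 857 upward and 939 downward, and 868 of them by at least 2-fold. The groups did not overlap in 72.1% of all tested genes, against 10% by chance. The direction counts were 909 upward and 784 downward after rescaling to TPM, 986 and 817 with quantile normalization, where the median log2 change was 0.12 against -0.04, and 844 and 816 with annotated genes alone, so which direction prevails depends on the scaling and the features.

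Ribosomal protein genes rose in 48 of 51 cases and fell in 1 (camera adjusted p = 3.25e-13, and adjusted p = 0.452 with an estimated correlation), with a median log2 change of 1. rplL went from 1993 ± 59.9 to 8100.2 ± 410.1 FPKM, a log2 change of 2.02 ± 0.13, and rpsG from 2841 ± 24.7 to 9979 ± 172 FPKM, a log2 change of 1.81 ± 0.08. All 8 ATP synthase genes rose, atpC by 0.87 ± 0.09 (adjusted p = 0.00404, and 0.513 with an estimated correlation). Fatty acid synthesis genes rose in 12 of 14 cases and fell in 0, with fabH, which starts chain elongation, at 1.97 ± 0.14 (adjusted p = 0.000145, and 0.346 with an estimated correlation). Pyrimidine genes rose in 8 of 9 cases, pyrB by 2.66 ± 0.18 (adjusted p = 0.000841, and 0.491 with an estimated correlation). Purine genes had 11 up and 2 down of 14 (adjusted p = 0.00878, and 0.491), and the 2 that fell, guaB (named after its values were seen) and xpt, act in guanine nucleotide supply. The fall of guaB, by -0.50 ± 0.19 (adjusted p = 0.0388), did not pass without any 1 of the LJN or BITC_RES libraries. Glycolysis had 9 up and 2 down of 12 (adjusted p = 0.0136, and 0.491 with an estimated correlation), with tpiA, for triosephosphate isomerase, at 2.43 ± 0.19. Sugar uptake had 13 up and 2 down of 19 (adjusted p = 0.0136, and 0.273), aminoacyl-tRNA synthetases 13 up and 3 down of 23 (adjusted p = 0.0199, and 0.624), and cysteine and methionine metabolism 4 up and 0 down of 5 (adjusted p = 0.0445, and 0.491).

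Downward calls in BITC_RES against LJN were made for 5 lists. Secreted proteases, lipases and nucleases fell in 13 of 16 cases (adjusted p = 6.73e-05), and this call held with an estimated correlation (adjusted p = 0.0362). Toxins fell in 6 of 7 cases (adjusted p = 7.79e-05, and 0.187 with an estimated correlation). Virulence regulators fell in 11 of 17 cases and rose in 4, among them the regulator gene saeR, chosen after its values were seen, by -2.18 ± 0.14 and rot by -3.71 ± 0.13 (adjusted p = 0.0489, and 0.491 with an estimated correlation). Oxidative stress defence fell in 10 of 14 cases and rose in 2, including msrA1, for methionine sulfoxide reductase, by -1.47 ± 0.12 and ahpC, for a peroxidase, by -0.99 ± 0.09 (adjusted p = 0.033, and 0.346 with an estimated correlation). Staphyloxanthin and SigB-linked genes fell in 5 of 8 cases (adjusted p = 0.0489, and 0.529 with an estimated correlation). Heat shock genes had no call, with 7 up and 5 down of 15 (adjusted p = 0.453), where groEL rose by 0.99 ± 0.09 and the ATPase gene clpL changed by -3.55 ± 0.21. The multidrug efflux list had 4 up and 0 down of 5 (adjusted p = 0.135), with mepA at 2.37 ± 0.18. The cell wall stress regulator genes vraR and vraS rose by 1.66 ± 0.10 and 1.56 ± 0.10. Adjusted over the list alone, counts differed from those over all genes for SOS response with 7 up and 9 down, the respiratory chain with 7 up, and stable RNAs with 9 up and 4 down. Median and mean differed in sign for heat shock (0.16 and -0.02), iron uptake (-0.17 and 0.26), TCA cycle (-0.04 and 0.01), fermentation (0.02 and -0.25), teichoic acid synthesis (-0.04 and 0.08) and capsule (0.27 and -0.81).

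**Figure D2:**
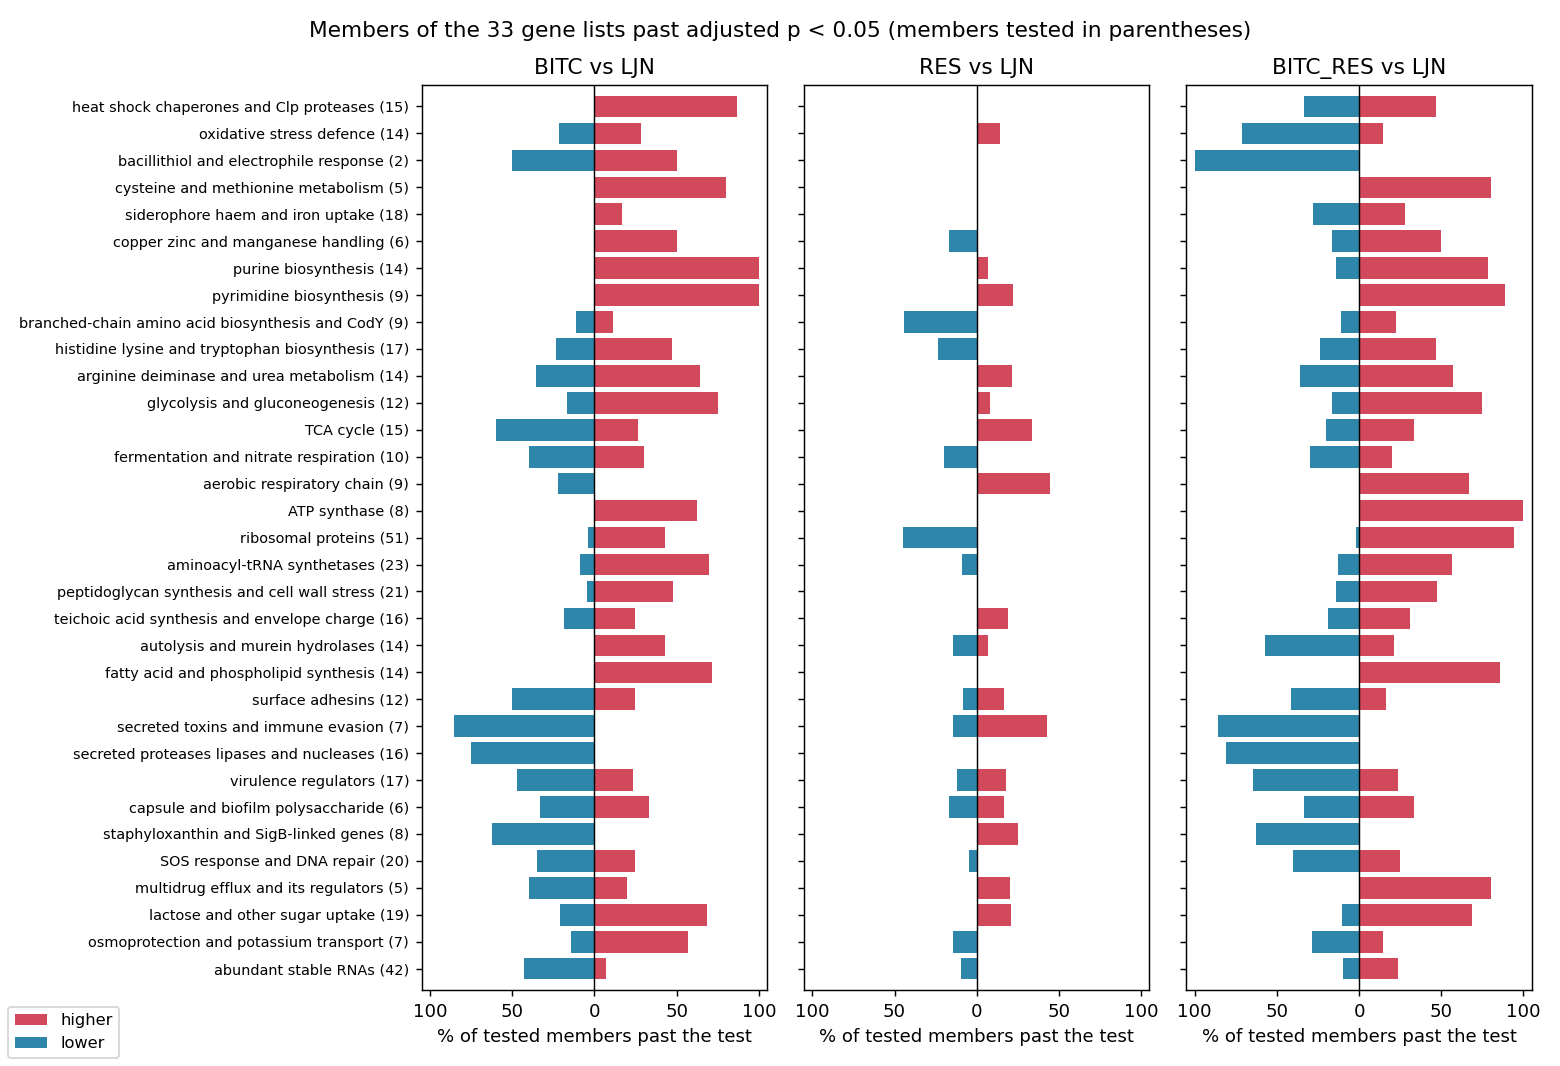
Percent of the tested members of each of the 33 gene lists that were higher (red, to the right) or lower (blue, to the left) than LJN at an adjusted p below 0.05, with the number of tested members in parentheses, for BITC, RES and BITC_RES. In BITC_RES 48 of 51 ribosomal protein genes were higher and 13 of 16 secreted protease, lipase and nuclease genes were lower, whereas 23 ribosomal protein genes were lower in RES.

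Adding resveratrol to benzyl isothiocyanate was read from BITC_RES against BITC. This holds only if benzyl isothiocyanate had the same dose and exposure time in both groups, which the sources used here do not give. The arginine deiminase genes, high in BITC, were below LJN levels in BITC_RES. arcA stood at 77.1 ± 6.89 FPKM, a log2 difference of -5.33 ± 0.31 from BITC (adjusted p = 4.89e-08), arcB at 68.5 ± 2.96 FPKM, a difference of -5.24 ± 0.23, and arcC2, for carbamate kinase, at 189 ± 19.8 FPKM, a difference of -5.18 ± 0.17. Against LJN, values looked up after these were seen, arcA, arcB and arcC2 in BITC_RES were lower by log2 changes of -1.38 ± 0.31, -1.44 ± 0.23 and -1.07 ± 0.17. hlgA and splA were lower than in BITC by -3.82 ± 0.13 and -4.96 ± 0.21, and clpL by -3.57 ± 0.21. SAOUHSC_03045, annotated as a cold shock protein, rose from 814 ± 95.3 to 28137 ± 3243 FPKM, a log2 change of 5.11 ± 0.15 (adjusted p = 2.54e-10). hrtB rose by 4.43 ± 0.25, the multidrug efflux gene mepA by 2.24 ± 0.18 and the lactate dehydrogenase gene ldh1 from 6208 ± 315 to 27810.4 ± 376 FPKM, a log2 change of 2.16 ± 0.12.

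Between BITC_RES and BITC 1601 genes changed, 820 upward and 781 downward, and 660 by at least 2-fold. The groups did not overlap in 62.8% of all tested genes, against 10% by chance. With annotated genes alone in the fit the direction counts were 694 and 760. After rescaling to TPM they were 613 and 930, and with each library's own read total 644 and 944. The median log2 change was then -0.16 and -0.15, against -0.01. Ribosomal protein genes rose in 40 of 51 cases and fell in 1, rplY by 1.92 ± 0.08 (adjusted p = 3.66e-11, and 0.496 with an estimated correlation). ATP synthase genes rose in 8 of 8 cases (adjusted p = 0.0308, and 0.809), but in 3 after rescaling to TPM or with quantile normalization, and fatty acid synthesis genes in 10 of 14 (adjusted p = 0.00318, and 0.496). Downward calls were made for toxins with 5 of 7 (adjusted p = 0.000326, and 0.173), secreted proteases with 11 down and 1 up of 16 (adjusted p = 0.0036, and 0.173) and the arginine and urea list with 12 down and 2 up of 14 (adjusted p = 0.0036, and 0.177). Oxidative stress defence had 9 down and 2 up of 14 (adjusted p = 0.00577, and 0.173), and autolysis 9 down and 1 up of 14 (adjusted p = 0.046, and 0.177), where the regulator genes lytR and lytS differed by -2.39 ± 0.26 and -1.89 ± 0.16. None of these 8 calls held with an estimated correlation, and fry made 23.

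Adding benzyl isothiocyanate to resveratrol was read from BITC_RES against RES. The same limit holds here for the dose and exposure time of resveratrol. The gamma-hemolysin gene hlgA, at 1505 ± 222 FPKM in RES and 4.50 ± 0.475 in BITC_RES, had the largest log2 difference of the named genes, -8.09 ± 0.13 (adjusted p = 1.24e-12). sarX, which encodes a repressor of the agr system, differed by -4.89 ± 0.21 and SAOUHSC_00195, for acetyl-CoA acetyltransferase, by -7.19 ± 0.27. The mannitol transporter gene mtlA rose by 3.99 ± 0.19, azoR, for azoreductase, by 2.71 ± 0.12 and SAOUHSC_00708, for a fructose permease, by 4.59 ± 0.20. In total 1802 genes changed, 881 upward and 921 downward, 844 by at least 2-fold, and the groups did not overlap in 69.9% of all tested genes, against 10% by chance. After rescaling to TPM the direction counts were 1050 and 697, and the median log2 change was 0.20 against -0.03. Ribosomal protein genes rose in 48 of 51 cases and fell in 2 (adjusted p = 4.01e-16, and 0.416 with an estimated correlation), and secreted proteases, lipases and nucleases fell in 13 of 16 (adjusted p = 5.08e-05, and adjusted p = 0.0335 with an estimated correlation), the 1 call of 13 that held.

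The single compounds were compared with each other in RES against BITC. Of the named genes, those higher in RES included sarX by 4.97 ± 0.21, rot by 3.38 ± 0.13, esxA, for a substrate of type VII secretion, by 3.90 ± 0.13, agrA by 2.70 ± 0.10 and hld, for delta-hemolysin, by 2.65 ± 0.14. arcA, ureA and azoR were higher in BITC, with log2 differences of -4.05 ± 0.31, -4.09 ± 0.29 and -3.21 ± 0.12. In total 1642 genes differed, 826 higher and 816 lower in RES, 596 by at least 2-fold, and the groups did not overlap in 62.0% of all tested genes, against 10% by chance. With annotated genes alone in the fit the direction counts were 722 and 789. After rescaling to TPM they were 437 and 1233, and with each library's own read total 613 and 991. The median log2 change was then -0.35 and -0.16, against 0.01. Virulence regulators had 8 higher and 4 lower of 17 (adjusted p = 0.084), and 6 and 7 after rescaling to TPM. Toxins were higher in RES in 6 of 7 cases (adjusted p = 0.000672, and 0.334 with an estimated correlation) and TCA cycle genes in 11 of 15 with 3 lower (adjusted p = 0.0436, and 0.521), or 7 and 4 after rescaling to TPM. Purine genes were lower in 14 of 14 (adjusted p = 2.95e-05, and 0.335) and ribosomal protein genes in 42 of 51 with 3 higher (adjusted p = 5.58e-08, and 0.43). Camera made 14 calls, none of which held with an estimated correlation.

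A contrast set the response to resveratrol with benzyl isothiocyanate (BITC_RES minus BITC) against that without it (RES minus LJN). It asked where both compounds together differed from the sum of their single responses on the log2 scale. This reading assumes that BITC_RES had the doses and exposure times of the single groups. They are not given in the sources used here, so a difference in dose or time cannot be told apart from a joint effect. hlgA had the largest contrast, -6.58 ± 0.19 (adjusted p = 4.41e-10), since it was 2.77 higher with resveratrol alone and differed by -3.82 when resveratrol was added to benzyl isothiocyanate. arcA, arcB, arcC2 and arcR, the regulator gene of the pathway, had contrasts of -5.24 ± 0.43, -5.23 ± 0.32, -5.32 ± 0.24 and -5.06 ± 0.18. The protease gene splA had -4.39 ± 0.29, psuG, for pseudouridine-5'-phosphate glycosidase, -4.23 ± 0.48, and the haem exporter gene hrtB 4.04 ± 0.35 (adjusted p = 2.94e-06). Ribosomal protein genes had positive contrasts in 47 of 51 cases and a negative one in 1, rplY at 2.02 ± 0.11 and rpsG at 1.65 ± 0.11 (adjusted p = 6.97e-16, and 0.335 with an estimated correlation).

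The contrast passed the test in 1321 genes, 676 positive and 645 negative, and in 710 of them by at least 2-fold. Of the 676, 173 were features with no annotated gene. The direction counts were 496 positive and 638 negative with annotated genes alone, 571 and 634 after rescaling to TPM, 631 and 661 with quantile normalization, and 589 and 681 with each library's own read total. Without BITC replicate 3 the count was 1402. Negative list calls were made for toxins with 6 of 7 (adjusted p = 5.19e-05, and 0.156 with an estimated correlation), secreted proteases with 8 of 16 (adjusted p = 0.00846, and 0.156), oxidative stress defence with 9 of 14 (adjusted p = 0.00846, and 0.16) and the arginine and urea list with 10 negative and 1 positive of 14 (adjusted p = 0.00238, and 0.16). Positive calls were made beside the ribosomal proteins for ATP synthase with 6 of 8, or 2 after rescaling to TPM and 1 with quantile normalization (adjusted p = 0.0287, and 0.738), fatty acid synthesis with 8 of 14 (adjusted p = 0.017, and 0.604) and stable RNAs with 17 positive and 1 negative of 42 (adjusted p = 0.0119, and 0.604). The stable RNA list was fixed as a sign of rRNA removal and RNA quality. All tRNA genes together held group means of 0.0261% (BITC) to 0.0558% (BITC_RES) of assigned reads in these libraries enriched for mRNA. In 2 genes chosen after their values were seen, the levels followed benzyl isothiocyanate and the contrast was not past the test. uhpT stood at 202 ± 41.8 FPKM in BITC and 189 ± 24.1 in BITC_RES against 21.5 ± 1.1 in LJN, with a contrast of -0.16 ± 0.22 (adjusted p = 0.581), and rot at 30.1 ± 3.52 and 29.5 ± 4.41 against 397 ± 41.2 FPKM, with a contrast of 0.27 ± 0.18 (adjusted p = 0.251).

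**Figure D3:**
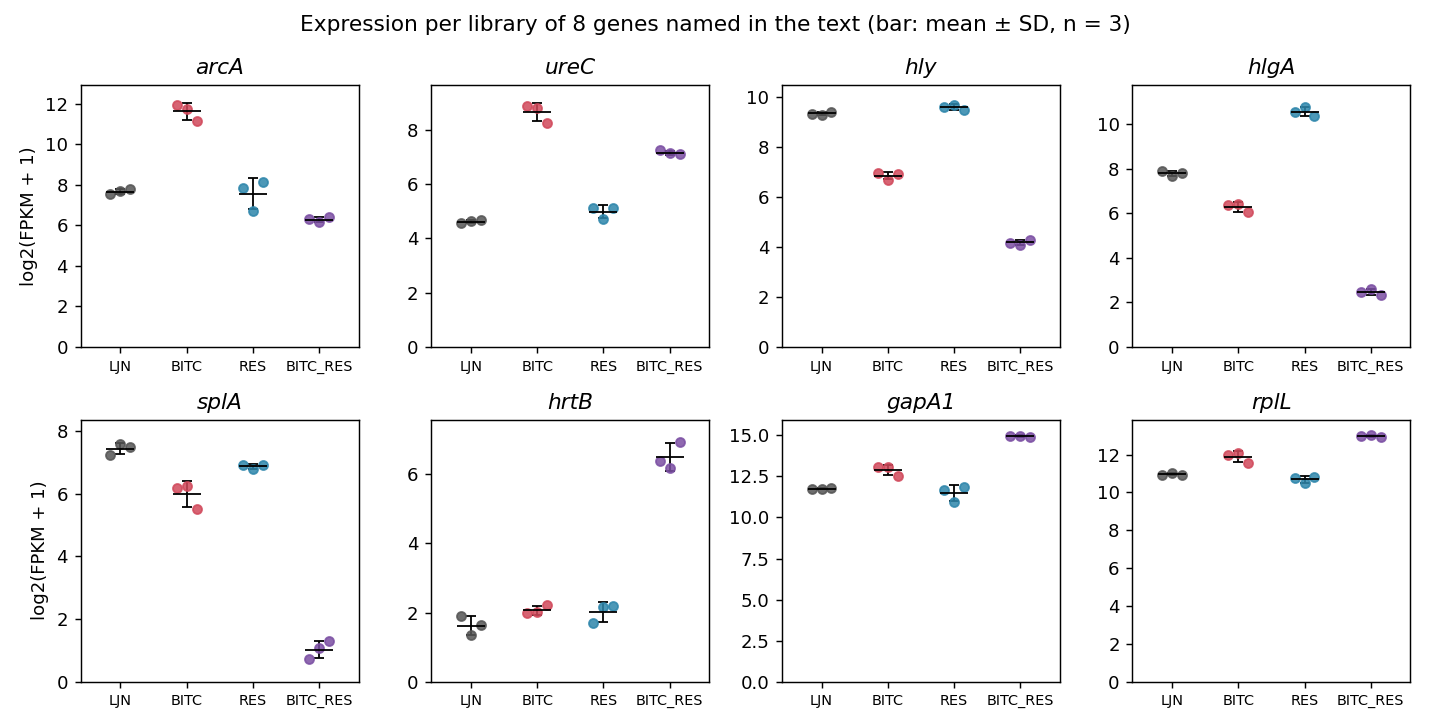
Expression as log2(FPKM + 1) of arcA, ureC, hly, hlgA, splA, hrtB, gapA1 and rplL in each library, by group, with points for single libraries and bars for the mean ± SD of 3 libraries. arcA is high in BITC alone, hlgA is high in RES and lowest in BITC_RES, and hrtB, gapA1 and rplL are highest in BITC_RES.

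Calls against LJN were compared between treatments. BITC and BITC_RES shared 480 genes that rose and 541 that fell, with 170 in opposite directions, where independent lists would share 248 and 284 genes (r of log2 changes across genes 0.62). BITC and RES shared 73 that rose and 145 that fell, with 86 in opposite directions, against 55.0 and 71.4 for independent lists (r 0.41). RES and BITC_RES shared 91 and 109, with 117 in opposite directions, against 59.1 and 80.4 (r 0.26). These comparisons use the same LJN libraries. Features with no annotated gene made up 202 of the 833 falls in BITC, 107 of 236 in RES and 127 of 939 in BITC_RES. Overlaps were not counted without these features. In simulations of unchanged groups that share controls, r was 0.49, and the shared calls averaged 0 rises and 0.01 to 0.02 falls. The same sign was seen in 55.9% of genes for BITC and RES, 70.2% for BITC and BITC_RES and 57.8% for RES and BITC_RES, and in 66.5% to 66.6% in the simulations. The simulated groups held no changed genes, so their r and sign shares come from the shared controls alone. They cannot be set against values from groups in which many genes changed. The covariance of the log2 changes was 0.872 for BITC and BITC_RES, 0.215 for BITC and RES and 0.163 for RES and BITC_RES. These lay above the 0.0286 to 0.0289 of the simulations, where noise was drawn for each gene on its own. Such noise holds no shift that many features of LJN share. Among unannotated features, falls against LJN outnumbered rises by 202 to 8 in BITC, 107 to 2 in RES and 127 to 24 in BITC_RES. The higher covariances therefore do not exclude a shift in the shared controls.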

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

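The scaling tests of the ribosomal genes, the tests for LJN RNA or a wrong label in BITC replicate 3 and the counts over other splits of the libraries were chosen after the result was seen, and the remaining tests were written before.

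The response to resveratrol differed with and without benzyl isothiocyanate by a test of the difference itself, which 1321 genes passed. Doses and exposure times are not given, so other doses or times in BITC_RES than in the single groups cannot be told apart from a joint effect. The named genes with the largest differences include genes of leukotoxins, arginine breakdown, a protease, haem export and pseudouridine breakdown. Their log2 contrasts were -6.58 for hlgA, -4.72 for hlgC and -4.24 for hlgB, -5.32 for arcC2, -5.24 for arcA, -5.23 for arcB and -5.06 for arcR, -4.39 for splA, -4.23 for psuG and 4.04 for hrtB. In 56 genes the level rose with resveratrol alone and fell with resveratrol on top of benzyl isothiocyanate, and in 102 genes it fell and rose. These counts were not split by feature type, and 173 of the 676 positive contrasts were features with no annotated gene. Of 100 splits of the libraries 2, the real one included, gave as many genes, a share under 0.05. Most random splits put libraries with and without benzyl isothiocyanate in the same group. That widens the spread within groups and lowers the count whether or not the contrast is real, so the share cannot decide about chance. The highest other split gave 1428 genes, and it parts all LJN and RES libraries from all BITC and BITC_RES libraries, so it follows the presence of benzyl isothiocyanate and not an unrelated grouping.

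For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count was 1631 genes for BITC against LJN, with 1 gene in the highest other split. For RES against LJN it was 426, for BITC_RES against LJN 1796, for BITC_RES against BITC 1601, for BITC_RES against RES 1802 and for RES against BITC 1642, and the highest other split of each gave 0 genes. The other splits hold libraries of both groups on each side, which widens the spread and by itself lowers their counts.

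The higher level of ribosomal protein genes in BITC_RES than in LJN was weighed against scaling and gene length. Over 4 scalings the lowest median log2 change of the list was 0.65 and the highest 1.12, against 1 as reported, which argues against scaling as the whole cause. Lists of other genes matched on length and level had a median of -0.27, and the highest of 10000 such lists reached 0.87, below the ribosomal list, which argues against short length. A candidate explanation that stays open, found and examined on the same data, is that cells given both compounds make more ribosomal transcripts relative to others. Growth rate, which sets ribosome synthesis in bacteria, was not analysed here.

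On the first principal component BITC replicate 3 lies between the other BITC libraries and LJN, and 10.05% of its reads fell on sRNA00010. That share would ask for 72.3% LJN RNA or 52.0% RES RNA. The median share of LJN RNA over 16 genes far above BITC replicates 1 and 2 was 0.0572%, and that of RES RNA over 13 such genes was -0.900%, which argues against a mixed sample as the cause. The highest correlation of this library with another group was 0.940, against 0.980 and 0.981 with its own, which argues against a wrong label. A weaker exposure or an earlier stage of the response may account for it, and no biological explanation was tested. The deviations of this library from its group means correlated at 0.392 with those of RES replicate 2, the highest value across groups. RES replicate 2 had 15.1% of its reads on sRNA00010, against 13.9% and 13.7% in the other RES libraries. By its label it was not given benzyl isothiocyanate, so a weaker exposure to that compound would leave this shared part unexplained.

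Features antisense to annotated genes were higher in LJN than in BITC, with 202 of 265 unannotated features lower in BITC and 8 higher. DNA in the LJN libraries would lift silent genes as well, yet 38.1% of annotated genes stood in LJN below the 29.4 FPKM that the median antisense feature lost, which argues against it. Weaker strand separation in LJN cannot be told apart from a change in antisense transcription. Across 164 features the antisense change followed the sense gene with a slope of 0.81 (95% interval 0.73 to 0.89, r 0.85, residual SD 0.58). For reads on the wrong strand, an interval that holds 1 and a residual SD under 0.5 had been set beforehand. An upper bound of the slope under 0.5 had been set as the cut-off against such reads, and neither was met. The median antisense change was -1.33 and that of the sense genes 0.02.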

How the results depend on the processing

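The alternatives with limma-voom, own read totals, annotated genes alone, other-species symbols and list tests without BITC replicate 3 were chosen after the result was seen. With a threshold of at least 2-fold, the counts were 645 for BITC against LJN, 118 for RES against LJN, 868 for BITC_RES against LJN, 660 for BITC_RES against BITC, 844 for BITC_RES against RES, 596 for RES against BITC and 710 for the contrast, since this asks more of each gene. Shared rises, shared falls and opposite calls were then 4, 74 and 4 for BITC and RES, 122, 265 and 32 for BITC and BITC_RES, and 2, 52 and 12 for RES and BITC_RES. Leaving out single libraries gave 1385 to 1736 genes for BITC against LJN, 180 to 623 for RES against LJN, 1652 to 1857 for BITC_RES against LJN, 1417 to 1636 for BITC_RES against BITC, 1641 to 1854 for BITC_RES against RES, 1366 to 1756 for RES against BITC and 1158 to 1402 for the contrast. For RES against LJN the count was 208 without LJN replicate 1, 180 without LJN replicate 3, 234 without RES replicate 1 and 276 without RES replicate 2, where fewer samples were compared. With the replicate number as a block the counts, in the order above, were 1552, 361, 1755, 1538, 1754, 1569 and 1232. With limma-voom they were 1638, 457, 1797, 1599, 1789, 1637 and 1322.

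With an estimated correlation the list calls were 0 for BITC against LJN, 0 for RES against LJN, 1 for BITC_RES against LJN, 0 for BITC_RES against BITC, 1 for BITC_RES against RES, 0 for RES against BITC and 0 for the contrast. The estimate was 0.803 for ATP synthase and 0.455 for ribosomal proteins, above the preset 0.01. For secreted proteases it was -0.00447, below the preset value. Their call in BITC against LJN was lost all the same (camera adjusted p = 0.00101, and 0.108 with the estimate). A correlation above the preset value therefore cannot account for every lost call, and the cause was not tested. With fry the list calls were 24, 5, 28, 23, 27, 27 and 17. With symbols from other species they were 15, 7, 11, 13, 13, 18 and 13 in this order, against 13, 6, 14, 8, 13, 14 and 8, and the cause was not tested. Without BITC replicate 3 they were 14, 6, 13, 9, 13, 15 and 9 in the order of the fry calls. Among the genes named, no log2 change reversed. Calls that an alternative ended were those of guaB in BITC_RES (adjusted p = 0.207 with TPM), argF in BITC (adjusted p = 0.109 with TPM and 0.279 with quantile normalization), and qoxD and sbi in RES, where the adjusted p of sbi without LJN replicate 3 was 0.124. The contrast of rot passed with quantile normalization (adjusted p = 0.0464). Ends of calls without a library come from fewer samples, and for the others the cause was not tested. Genes near 1 FPKM are limited by depth, since few reads cover them.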

Other observations

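The gene groups in this part were chosen after their values were seen. Genes of the type VII secretion system, which exports small virulence proteins, lie from esxA to essD at 275931 to 289414, and 10 of 11 were tested. All 10 fell in BITC, with a median log2 change of -1.77, and all 10 fell in BITC_RES, with a median of -2.30, while the median in RES was -0.01. The substrate gene esxA went from 826 ± 128 FPKM in LJN to 48.0 ± 5.26 in BITC and 59.5 ± 8.78 in BITC_RES. The 14 genes from cap5A to SAOUHSC_00127 at 119492 to 133522, for capsule synthesis, all fell in BITC (median -1.79) and in BITC_RES (median -2.27), and 4 of them fell in RES (median -0.76). Of 34 genes with phage in the product name 13 were tested, of which 10 fell and 2 rose in BITC (median -2.60), and 11 fell and 2 rose in BITC_RES (median -2.76).

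The 5 genes from SAOUHSC_00195 to SAOUHSC_00199 at 214246 to 222338 include an acetyl-CoA acetyltransferase and a CoA transferase, enzymes of short-chain acyl-CoA use. All 5 fell in BITC_RES, with a median log2 change of -5.79, and all 5 had negative contrasts between the responses to resveratrol with and without benzyl isothiocyanate, with a median of -4.97. SAOUHSC_00195 stood at 673 ± 34.3 FPKM in LJN, 412 ± 209.5 in BITC, 1220.4 ± 235 in RES and 7.32 ± 1.36 in BITC_RES. SAOUHSC_02243, whose protein hit is a leukocidin-like protein, went from 588 ± 13.6 FPKM in LJN to 6.90 ± 2.22 in BITC and 2.32 ± 0.503 in BITC_RES. SAOUHSC_02866, with a hit to a membrane protein of the MMPL family, rose in each treatment, from 5.66 ± 0.510 FPKM in LJN to 13.4 ± 2.66 in BITC, 36.8 ± 1.95 in RES and 226 ± 16 in BITC_RES.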
